A study of Mus musculus with 18 samples.

How the data were processed

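RNA was measured in CD4 and CD8 T cells that were purified from mouse bone marrow by fluorescence-activated sorting. The labels name 3 kinds of mice, with 3 mice each: C57BL/6 mice given zinc-enriched drinking water for 30 days, pMT-10 mice given the same water, and pMT-10 mice given control water. The pMT-10 strain carries an IL-10 transgene under a metallothionein promoter, which zinc switches on. This gave 18 libraries in 6 groups of 3. Libraries were made with the Ion AmpliSeq Transcriptome Mouse Gene Expression Kit, a targeted panel that amplifies a short piece of each transcript. The deposited values are raw read counts per amplicon, with 1 amplicon for each of 23930 genes, and the authors applied no scaling to them. The submitters' processing notes give the genome build as mm10, and the aligner and the counting tool are not given in the sources used here. No molecular identifiers are named, so limits from a count of 0 cover counting error only.

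Total counts per library ran from 10546798 to 18519474, and the 10 most abundant genes took from 9.1 to 12.6% of them. At this depth 1 CPM by total counts, before TMM scaling, stood for 10.5 to 18.5 reads. Every column of the count files was mapped to a sample by its barcode. Replicate numbers follow the order of the sample records and carry no other meaning. All 12 libraries of zinc-fed mice were sequenced on 1 chip and all 6 libraries of pMT-10 mice without zinc on another, so chip and zinc cannot be told apart. The libraries of C57BL/6 mice held reads of Y-linked genes and those of pMT-10 mice held Xist reads instead, so sex differed together with strain.

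Low counts were removed with filterByExpr, which left 11316 genes. Counts were scaled with TMM factors and fitted in edgeR 4.0.16 under R 4.3.3 by the quasi-likelihood method with robust estimation, using 6 group means over all 18 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and adjusted p values in the text come from this test unless another is named. Log2 fold changes are the fitted values with their standard errors (SE). CPM values use TMM-scaled library sizes and are given as mean ± SD of 3 replicates. Folds are ratios of mean CPM. Where every replicate of a group had 0 counts, the fold is given as "at least". It is then the ratio of counts pooled over the libraries of a group to 3 counts over the group at 0, per effective library size, and differs a little from a ratio of mean CPM. Leaving out a library of the group at 0 changes only the limit, through its depth, so bounds were repeated without each library of the other group. No fold is printed for 1 to 3 counts. Exact two-sided permutation tests of 3 against 3 cannot go below 0.1. A gene was said to be without overlap when every replicate of a group lay above every replicate of the other, which 10% of unchanged genes would show by chance.

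The comparisons were zinc-fed pMT-10 against zinc-fed C57BL/6, zinc-fed pMT-10 against pMT-10 without zinc, and the control groups against each other, each in CD4 and in CD8 cells. The difference between cell types was tested in each kind of mouse. An interaction contrast tested whether the difference between zinc-fed pMT-10 and zinc-fed C57BL/6 mice was the same in both cell types. Genes called in the same direction against both controls, and in both cell types, were counted. Each of these overlaps was set beside the product of the call counts divided by the genes tested, and the overlaps against both controls also beside 20 simulated data sets of unchanged groups that shared the zinc-fed pMT-10 libraries.

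Before the data were examined, 33 gene lists were fixed, and 28 of them had at least 5 tested members and so a set test. The functional lists covered T cell identity, CD4 lineage, CD8 lineage, cytokines made by T cells, type 1 and cytotoxic effector genes, naive and quiescence genes, activation and residency genes, coinhibitory receptors and exhaustion genes, regulatory T cells, helper subsets other than type 1, type I interferon-stimulated genes, the interferon-gamma response, IL-10 and STAT3 signalling, the zinc response, the cell cycle, glycolysis, cholesterol synthesis, trafficking receptors, apoptosis regulators, and immediate early and heat shock genes. The marker lists covered neutrophils and their precursors, monocytes and macrophages, erythroid cells, B cells, plasma cells, NK cells, dendritic cells, stem and progenitor cells, mast cells with basophils and eosinophils, platelets and megakaryocytes, stroma and endothelium, gamma-delta and innate-like T cells, and sex-linked genes. Sets were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. A list is said to pass when its camera adjusted p at the preset correlation was under 0.05, unless another test is named. Members were also adjusted over the list alone.

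The genes named were chosen by a rule fixed before the data were examined. For each contrast of zinc-fed pMT-10 mice with a control, the rule took the 8 largest rises and 8 largest falls among called genes without overlap and with a mean of at least 10 CPM in the higher group. It always took Il10, Ifng, Tnf, Csf2, Tbx21, Gzmb, Mt1, Socs3 and Mki67, and Mt2 was not analysed here. From each list with a called member or a passing set test it took up to 4 members with the smallest p. For the cell type contrasts it took Cd4, Cd8a, Cd8b1 and the 5 largest changes in each direction, and for the interaction the 8 genes with the smallest p. Between the control groups every called gene was named. Foxp3, Ccl5 and members that moved against the rest of their list were named after their values were seen. Gene coordinates came from GENCODE M21 on GRCm38 (mm10), which matched 10789 of the tested genes by symbol.

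Alternatives fixed before the data were examined were RLE size factors, library size only, no filter, a stricter filter of 50 counts in 3 samples, DESeq2 1.42.0, limma-voom with sample quality weights, robust estimation off, a fit to the 9 libraries of a cell type or to the groups compared only, an adjusted p of 0.01, a 2-fold minimum, leaving out each library in turn, and CPM by total counts. Leaving out genes on X and Y, and leaving out zinc-fed C57BL/6 CD4 replicates 2 and 3 together, were chosen after seeing the data. The pipeline was tested on simulated data with the group sizes of the CD4 contrast. It recovered 5 of 67 genes changed 1.5-fold (7.46%), 34 of 67 changed 2-fold (50.8%) and 48 of 66 changed 4-fold (72.7%). It also called 8 unchanged genes of 11071 tested, a larger share of the calls than the threshold of 0.05 aims at. Far fewer genes were changed than the 2115 called in the real CD4 contrast, so these recovery shares need not hold there. Figures were drawn with matplotlib 3.10.9.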

Results

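RNA was read out with a targeted amplicon panel of 23930 mouse genes in 18 libraries of CD4 and CD8 T cells sorted from bone marrow. The 6 groups of 3 libraries came from zinc-fed C57BL/6 mice, from zinc-fed pMT-10 mice, whose IL-10 transgene zinc switches on, and from pMT-10 mice without zinc, each with a CD4 and a CD8 group. Total counts per library ran from 10546798 to 18519474. Log2 CPM of replicates correlated across genes at r of 0.974 to 0.988, though genes are not independent replicates. The first principal component (43.6% of the variance) separated CD4 from CD8 libraries, and the second (17.1%) placed the libraries of zinc-fed pMT-10 mice apart from both control groups in each cell type.

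The first question was whether the groups carried what their labels state. Cd4, the coreceptor that defines the sort, stood at 2190 ± 109 CPM in CD4 cells and 3.14 ± 2.21 CPM in CD8 cells of zinc-fed C57BL/6 mice (SD, n = 3 each), and Cd8a stood at 4.99 ± 4.37 and 2410 ± 153 CPM. Il10 (chromosome 1, 131019845 to 131024974, GRCm38) had 0 counts in all 6 control CD8 libraries and 12.8 ± 9.62 CPM in CD8 cells of zinc-fed pMT-10 mice. In CD4 cells it stood at 21.2 ± 4.71 CPM in zinc-fed pMT-10, 6.13 ± 2.76 CPM in zinc-fed C57BL/6 and 2.71 ± 1.16 CPM in pMT-10 mice without zinc. Mt1, a metallothionein gene that metals induce, stood at 10.9 ± 2.26, 4.42 ± 1.26 and 0.782 ± 0.569 CPM in the same order, and was not called against zinc-fed C57BL/6 (adjusted p = 0.185). In CD8 cells Mt1 stood at 3.11 ± 1.06, 0.4 ± 0.203 and 0.28 ± 0.44 CPM, and the control groups did not stand apart (exact permutation p = 0.8). There Mt1 was called against zinc-fed C57BL/6 (log2 2.93, SE 0.77, adjusted p = 0.0199). Both strains were given zinc, but an equal response of their cells to it cannot be assumed. Exact two-sided permutation tests of zinc-fed pMT-10 against either control gave p = 0.1 for Il10 in both cell types, the smallest value that 3 against 3 allows. The panel has 1 amplicon for each gene, so these counts do not say whether Il10 reads came from the transgene or from the mouse's own gene.

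**Figure D1:**
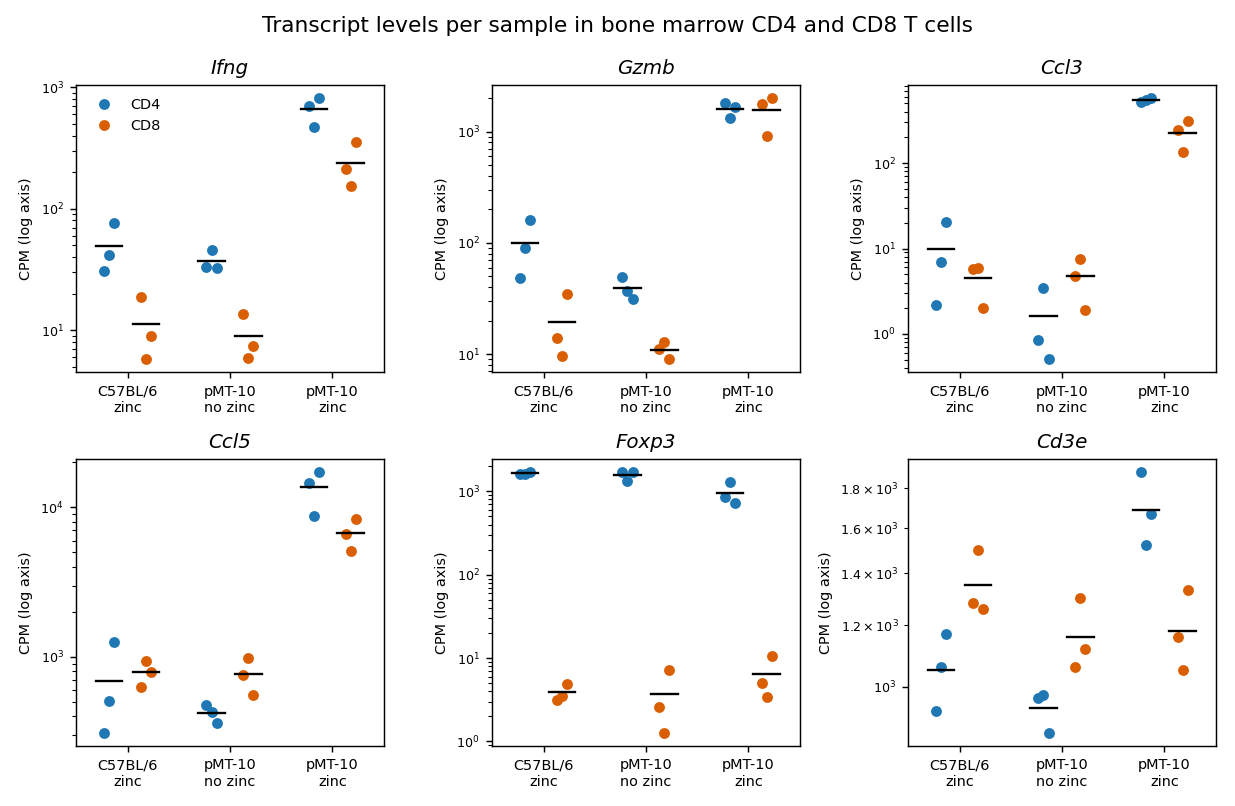
CPM of selected genes on a log axis in each of the 18 libraries, grouped by cell type and kind of mouse, with a point for each library and a line at each group mean. In CD4 cells Ifng averaged 662 CPM in zinc-fed pMT-10 mice against 49.6 and 37 CPM in the control groups, and in CD8 cells 240 against 11.2 and 8.95 CPM.

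CD4 cells of zinc-fed pMT-10 and zinc-fed C57BL/6 mice were compared to ask what IL-10 overexpression does to bone marrow CD4 T cells. Zinc feeding and chip were the same in both groups, while strain and sex differed. Genes of an interferon-gamma-producing, cytotoxic T cell rose, though not all of them. Ifng, the gene of interferon gamma (chromosome 10, 118441046 to 118445892), rose from 49.6 ± 24.1 to 662 ± 178 CPM (n = 3 each, log2 3.74, SE 0.46, adjusted p = 3.16e-05). Gzmb, the gene of a killer-cell protease (chromosome 14, 56258838 to 56262260), rose from 99.3 ± 56.1 to 1600 ± 253 CPM, or 16.1-fold (adjusted p = 3.24e-05). Eomes, a transcription factor of effector and memory T cells (chromosome 9, 118478212 to 118486132), rose from 20.2 ± 8.33 to 335 ± 46.9 CPM (adjusted p = 1.42e-08). The chemokine genes Ccl3 and Ccl4 rose 55.3-fold and 33.7-fold, folds that were 120 and 57.7 without zinc-fed C57BL/6 replicate 3, and Ccl5 averaged 13600 ± 4370 CPM against 694 ± 502 CPM. For Ifng, Gzmb and Eomes all 3 zinc-fed pMT-10 libraries stood above all 3 of zinc-fed C57BL/6, which chance alone gives for 10% of genes in some direction. Tbx21, the master factor of type 1 T cells, stood at 62.2 ± 6.47 against 44.4 ± 10.2 CPM (log2 0.48, adjusted p = 0.115), Csf2 at 0.202 ± 0.233 against 0.732 ± 1.2 CPM (log2 -1.75, adjusted p = 0.514) and Socs3 at 2.22 ± 0.857 against 0.879 ± 0.469 CPM (adjusted p = 0.249).

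In all, 2115 of 11316 genes were called between these CD4 groups, 1051 higher and 1064 lower in zinc-fed pMT-10. With a 2-fold minimum the counts were 470 and 581. Of 28 type 1 and cytotoxic effector genes, 17 rose and 5 fell (18 and 5 adjusted over the list alone), with a camera adjusted p of 2.3e-06 that did not hold with an estimated correlation (adjusted p = 0.179). Nkg7, a granule protein gene, rose 14.1-fold (22.9-fold without zinc-fed C57BL/6 CD4 replicate 3) and Id2 rose 4.55-fold, while the 5 that fell were the NK receptor genes Klrd1, Klrk1, Klrc1 and Klrc2 and the interleukin-12 receptor gene Il12rb2. Of 24 interferon-gamma response genes, 20 rose and 0 fell (22 over the list alone, camera adjusted p = 1.05e-13, and 0.0346 with an estimated correlation). Among them were Irf1 (2.6-fold, from 676 ± 50.8 to 1760 ± 10.1 CPM) and the antigen-presentation genes Nlrc5 (2.03-fold) and Tapbp (1.94-fold). Of 15 coinhibitory receptor and exhaustion genes, 9 rose and 1 fell (11 and 2 over the list alone, camera adjusted p = 0.000185, and adjusted p = 0.198 with an estimated correlation). Lag3 rose 16.9-fold (26.6-fold without that replicate), Havcr2 17.2-fold and Tox 2.19-fold, and Ctla4 fell by 1.25 on the log2 scale.

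Genes that keep T cells naive or quiescent fell. Of 18 such genes, 16 fell and 0 rose (18 over the list alone, camera adjusted p = 1.05e-13, and adjusted p = 0.138 with an estimated correlation). Klf2 fell by 1.73 on the log2 scale, Il7r, the interleukin-7 receptor gene, by 1.69, Foxp1 by 1.37 and Satb1 by 1.24. The ratio of mean CPM for Il7r was 0.311, and 0.202 without zinc-fed pMT-10 CD4 replicate 2. Of 13 regulatory T cell genes, 5 fell and 2 rose (8 and 2 over the list alone, camera adjusted p = 0.00776, and adjusted p = 0.14 with an estimated correlation). Ikzf2, Nrp1 and Gpr83 fell by 1.61, 2.56 and 2.51, whereas Rgs1 rose 2.38-fold. For Gpr83 the ratio of mean CPM was 0.177, and 0.107 without zinc-fed pMT-10 CD4 replicate 2. Foxp3, the defining factor of regulatory T cells, averaged 963 ± 294 CPM against 1660 ± 52.4 CPM and did not pass in the fit to all libraries (adjusted p = 0.151). Its 3 zinc-fed pMT-10 libraries (735 to 1290 CPM) still stood below the 3 of zinc-fed C57BL/6 (1620 to 1720 CPM, exact permutation p = 0.1). Of 12 glycolysis genes 8 rose and 0 fell (10 over the list alone, camera adjusted p = 4.13e-05, and 0.0335 with an estimated correlation), with Pfkp up 2.61-fold and Pkm 1.61-fold. Of 29 cell cycle genes 11 rose and 0 fell (15 over the list alone, camera adjusted p = 4.3e-08, and adjusted p = 0.138 with an estimated correlation), among them Top2a (2.91-fold) and Mcm6 (1.69-fold).

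Of 12 T cell identity genes 5 rose and 0 fell (8 over the list alone, camera adjusted p = 0.00107, and adjusted p = 0.0924 with an estimated correlation), with Cd3g up 1.78-fold and Lat 2.06-fold. Of 18 IL-10 and STAT3 signalling genes 9 rose and 3 fell (9 and 4 over the list alone, camera adjusted p = 0.00776, and adjusted p = 0.0728 with an estimated correlation), with Bcl3 up 3.09-fold, Sbno2 up 2.38-fold and the cytokine receptor gene Il6st down by 1.39 on the log2 scale. Of 21 activation and residency genes 10 rose and 1 fell (10 and 4 over the list alone). Ly6a, a surface antigen gene that interferons raise, rose 3.8-fold and Batf 2.52-fold. The camera adjusted p of this list, 0.0253, did not hold with an estimated correlation (adjusted p = 0.348), without zinc-fed C57BL/6 CD4 replicate 2 (0.0517) or without zinc-fed pMT-10 CD4 replicate 2 (0.311). The remaining functional lists did not pass by camera. By fry, trafficking receptors (adjusted p = 0.0229) and immediate early and heat shock genes (0.0366) passed, and the others tested did not. Trafficking receptors (6 rose, 8 fell of 19, adjusted p = 0.238) included Itgal up 2.64-fold and Itga6 down by 1.71. Type I interferon-stimulated genes (7 rose, 6 fell of 30, adjusted p = 0.784) included Mx1 up 3.08-fold and Slfn5 down by 1.82, and camera's direction was up while the median (-0.141) and mean (-0.111) were below 0. Helper subset genes (3 rose, 4 fell of 14, adjusted p = 0.554) included Rora up 3.44-fold and Il1rl1 down by 2.41. For Il1rl1 the ratio of mean CPM was 0.19, and 0.123 without zinc-fed pMT-10 CD4 replicate 2.

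Cytokine genes split, with 3 of 17 risen and 2 fallen (adjusted p = 0.561). Fasl, a death ligand gene, rose 5.52-fold and Lta fell by 1.51 on the log2 scale, and Tnf stood at 3.96 ± 0.524 against 2.73 ± 0.922 CPM (adjusted p = 0.552). Il10 itself rose 3.45-fold (adjusted p = 0.0319). Apoptosis regulators (3 rose, 2 fell of 12, adjusted p = 0.786, with camera and mean up but a median of -0.016) included Bcl2l1 down by 1.1. Immediate early and heat shock genes (1 rose, 4 fell of 16, adjusted p = 0.129) included Egr1 up 2.92-fold and Ier2 down by 0.71. Cholesterol synthesis genes (0 rose, 1 fell of 14, adjusted p = 0.84) and zinc response genes (0 of 7 called, adjusted p = 0.612) showed little. Of 4 CD4 lineage genes 2 fell, Tnfsf8 by 2.52 (ratio of mean CPM 0.176, and 0.1 without zinc-fed pMT-10 CD4 replicate 2). Of 3 CD8 lineage genes Runx3, a factor of cytotoxic T cells, rose 2.97-fold. Cd4 stood at 3250 ± 132 against 2190 ± 109 CPM. It was not called in the fit to all libraries (adjusted p = 0.295) and was called in the fit to CD4 libraries alone (adjusted p = 0.000189).

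Outside the lists, Ociad2 rose from 0.208 ± 0.197 to 31 ± 11.2 CPM, and Gcg rose 36.4-fold (104-fold without zinc-fed C57BL/6 CD4 replicate 3). Dntt, the gene of a lymphocyte precursor enzyme, fell by 4.2 on the log2 scale, Gpr15, a homing receptor gene, by 3.66 and Cd83 by 3.63. The ratio of mean CPM for Cd83 was 0.0817, and 0.0503 without zinc-fed pMT-10 CD4 replicate 2. Sostdc1, a member of the helper subset list, fell by 7.89. Its reads in zinc-fed pMT-10 CD4 cells came from replicate 2 alone, so that value is no bound. Of the Y-linked genes, Eif2s3y and Kdm5d had 0 counts in zinc-fed pMT-10 CD4 cells, lower by at least 1160-fold and 312-fold, and Ddx3y and Uty had 1 count each. The 5 sex-linked genes were all called (camera adjusted p = 1.19e-08, and 0.00129 with an estimated correlation). Markers of other cells were mostly sparse, and no other marker list passed by camera. By fry the monocyte (adjusted p = 0.00114), gamma-delta and innate-like (0.00135), stem and progenitor (0.00206), dendritic (0.0053) and plasma cell lists (0.0311) passed. The neutrophil, erythroid, NK and platelet lists did not pass by fry either. The monocyte list (4 of 8 rose, adjusted p = 0.144) held the chemokine receptor gene Ccr2 at 175 CPM as its most abundant member, up 2.85-fold. The NK list (2 rose and 4 fell of 10, adjusted p = 0.238) held Klrb1f up 8.59-fold and Klra9 down by 3.33. The dendritic list (2 of 7 rose, adjusted p = 0.11) held Irf8 up 3.48-fold. The B cell list held Cd74 at 391 CPM and Cd79b, down by 1.64 (ratio of mean CPM 0.325, and 0.196 without zinc-fed pMT-10 CD4 replicate 2). The neutrophil list had 0 of 5 called (adjusted p = 0.708), erythroid 2 of 7 up (0.388), plasma cell 1 of 5 up (0.612, median 0.022 but mean -0.629), stem and progenitor 2 up and 1 down of 5 (0.331) and gamma-delta and innate-like 1 of 5 down (0.245). The platelet list had 1 of 5 down (0.842, with camera down but a median of 2.68), and its genes Pf4 and Ppbp averaged 23.8 ± 40.9 and 22.7 ± 39 CPM because of 1 library. Neither of the 2 mast cell genes was called, and both of the 2 stroma and endothelium genes fell, Pecam1 by 2.11.

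Of 107 named genes called in this CD4 contrast, 91 stayed called without any single library. The call of Il10 ended without zinc-fed C57BL/6 CD4 replicate 1 (adjusted p = 0.0744) or 2 (0.132) and without zinc-fed pMT-10 CD4 replicate 1 (0.105) or 3 (0.0699), while its log2 change, 1.79 with all libraries, was 1.91, 1.46, 1.64 and 1.8 in these fits. The number of called genes fell from 2115 to 1377 without zinc-fed pMT-10 CD4 replicate 1, and scaling by library size only split the calls into 831 higher and 1448 lower.

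**Figure D2:**
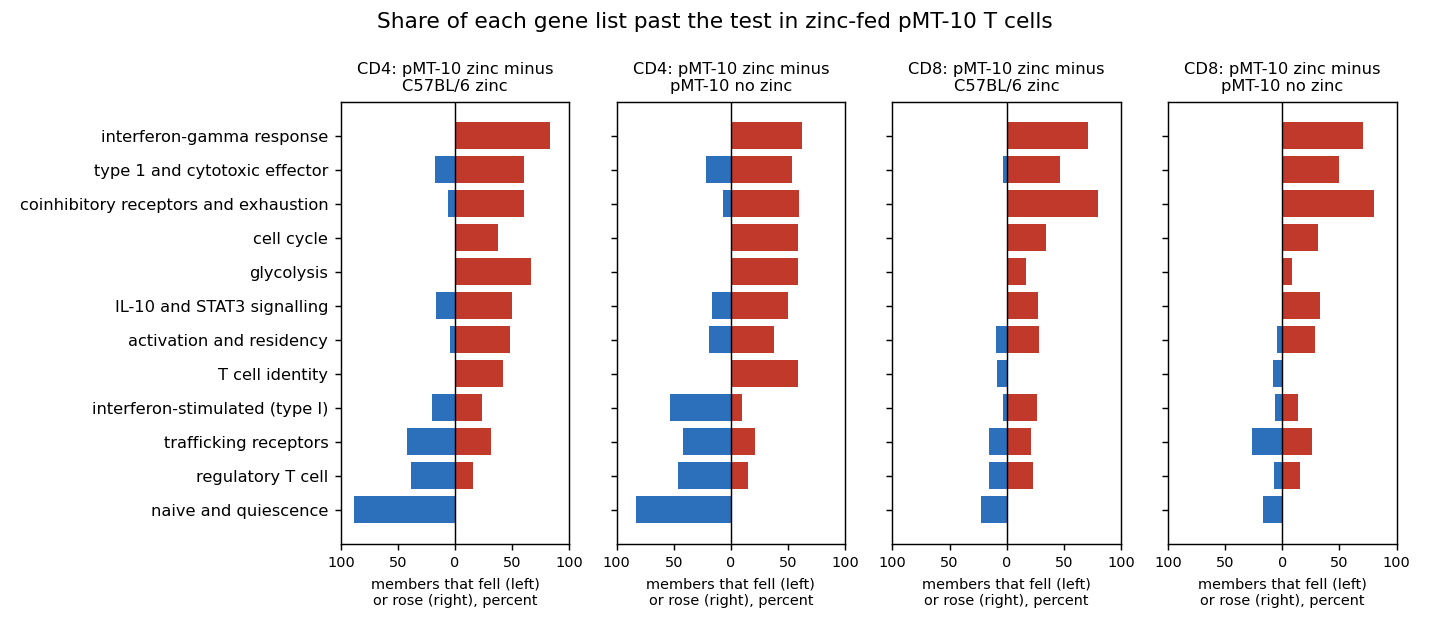
Percent of the tested members of selected functional lists called higher or lower in zinc-fed pMT-10 mice, for CD4 and for CD8 cells. Separate panels set these mice against zinc-fed C57BL/6 mice and against pMT-10 mice without zinc. Against zinc-fed C57BL/6, 20 of 24 interferon-gamma response genes rose and 16 of 18 naive and quiescence genes fell in CD4 cells. In CD8 cells 17 and 4 did so.

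The same comparison in CD8 cells, zinc-fed pMT-10 against zinc-fed C57BL/6, asked what IL-10 overexpression does to bone marrow CD8 T cells. Gzmb rose from 19.5 ± 13.4 to 1560 ± 571 CPM (n = 3 each), or 79.9-fold (log2 6.3, SE 0.54, adjusted p = 2.9e-06, higher in 3 of 3 libraries). Ifng rose from 11.2 ± 6.78 to 240 ± 100 CPM, or 21.5-fold (adjusted p = 2.52e-05), and Csf1, the gene of a growth factor for macrophages (chromosome 3, 107741048 to 107760469), 23.8-fold. Il10 was at least 163-fold higher by pooled counts. Receptors that restrain T cells rose with them: Lag3 62.1-fold, Pdcd1, the gene of PD-1, 26.7-fold, and Tigit 19.4-fold. Some of these folds leaned on 1 library. They were 131 for Gzmb and 41.5 for Csf1 without zinc-fed C57BL/6 CD8 replicate 3, 32.5 for Ifng and 47.2 for Pdcd1 without its replicate 1, and at least 107 for Il10 without zinc-fed pMT-10 CD8 replicate 1.

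In these CD8 groups 997 genes were called, 643 higher and 354 lower, and with a 2-fold minimum 417 and 86. Of 15 coinhibitory receptor and exhaustion genes 12 rose and 0 fell (14 over the list alone, camera adjusted p = 4.79e-16, and 0.0134 with an estimated correlation), including Maf (5.53-fold) and Rgs16 (23.1-fold). Of 24 interferon-gamma response genes 17 rose and 0 fell (20 over the list alone, camera adjusted p = 1.69e-21, and 0.0092 with an estimated correlation). The guanylate-binding protein genes Gbp4 and Gbp3 rose 3.59-fold and 2.58-fold, Gm12250 4.78-fold and Irf1 2.92-fold. Of 28 type 1 and cytotoxic effector genes 13 rose and 1, Klrc2, fell (17 and 1 over the list alone, camera adjusted p = 2.6e-09, and adjusted p = 0.0956 with an estimated correlation), among them Id2 (4.14-fold), Ccl4 (18.8-fold) and Prdm1 (17.7-fold). Tbx21 stood at 66.3 ± 4.01 against 64.8 ± 20.1 CPM (adjusted p = 0.957). Of 29 cell cycle genes 10 rose and 0 fell (16 over the list alone, camera adjusted p = 3.79e-10, and adjusted p = 0.0817 with an estimated correlation), with Mki67 up 10.7-fold, Top2a 4.93-fold and Birc5 12.3-fold.

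Type I interferon-stimulated genes rose too, 8 of 30, with 1 fallen (14 and 1 over the list alone, camera adjusted p = 4.15e-06, and adjusted p = 0.116 with an estimated correlation). Zbp1 rose 2.33-fold and Rtp4 2.14-fold. The list also stood higher in pMT-10 CD8 cells without zinc than in zinc-fed C57BL/6 (median log2 0.302, camera adjusted p = 3.47e-07, and 0.224 with an estimated correlation). Against pMT-10 without zinc it did not pass (median 0.151, camera adjusted p = 0.127), so its rise cannot be put down to IL-10 alone. Of 18 IL-10 and STAT3 signalling genes 5 rose and 0 fell (7 and 1 over the list alone, camera adjusted p = 0.0144, and adjusted p = 0.079 with an estimated correlation), with Bcl3 up 3.01-fold and Il10ra, the IL-10 receptor gene, 2.88-fold. Of 18 naive and quiescence genes 4 fell and 0 rose (6 over the list alone, camera adjusted p = 0.000712, and adjusted p = 0.594 with an estimated correlation), and Ccr9, a gut homing receptor gene, fell by 1.7 on the log2 scale. Of 21 activation and residency genes 6 rose and 2 fell (7 and 3 over the list alone), with Ly6a up 12.7-fold, Bhlhe40 10.5-fold and Irf4 2.4-fold. The adjusted p of that list, 0.0377, did not hold with an estimated correlation (adjusted p = 0.46). It was also lost without zinc-fed C57BL/6 CD8 replicate 1 (0.15) or 2 (0.052) and without zinc-fed pMT-10 CD8 replicate 1 (0.0628) or 3 (0.0951). Cytokine genes (4 rose, 3 fell of 17, adjusted p = 0.448, median 0 but mean 0.945), regulatory T cell genes (3 rose, 2 fell of 13, 0.448) and glycolysis genes (2 of 12 rose, 0.448) did not pass, nor did T cell identity (1 of 12 fell, 0.477, median 0.026 but mean -0.075). Trafficking receptors (4 rose, 3 fell of 19, 0.943, camera down but mean 0.192) included Cxcr4, a bone marrow retention receptor gene, down by 0.88. Helper subset genes (2 rose, 1 fell of 14, 0.659, camera up but mean -0.093) included Rora up 4.47-fold.

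Among markers of other cells in CD8 libraries, the monocyte list passed with 3 of 8 genes up (adjusted p = 0.00777), and not with an estimated correlation (adjusted p = 0.057). It was lost without zinc-fed C57BL/6 CD8 replicate 2 (0.0663) or zinc-fed pMT-10 CD8 replicate 3 (0.0828). Lgals3, a galectin gene that activated T cells also express, rose 25-fold to 7.72 ± 2.24 CPM, and the most abundant member, Cd68, stood at 21.3 CPM. The plasma cell list (2 of 5 up, adjusted p = 0.0377, and adjusted p = 0.098 with an estimated correlation) passed through Prdm1 and Irf4, which effector T cells also use. It was lost without any of the 6 libraries, with adjusted p of 0.0972, 0.0745 and 0.142 without zinc-fed C57BL/6 CD8 replicates 1, 2 and 3 and 0.127, 0.0792 and 0.11 without those of zinc-fed pMT-10. Irf8 rose 5.91-fold, Cd74 6.01-fold and Slamf1, a lymphocyte signalling receptor gene, 3.33-fold.

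Of 80 named genes called in the CD8 contrast, 60 stayed called without any single library, and the call count fell from 997 to 587 without zinc-fed C57BL/6 CD8 replicate 3. Scaling by library size only split the calls into 731 higher and 245 lower.

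Zinc-fed pMT-10 mice were next compared with pMT-10 mice without zinc, which asks what switching on the transgene does within 1 strain, although zinc and chip differ as well. In CD4 cells the same effector genes rose. Ifng rose from 37 ± 7.26 to 662 ± 178 CPM (n = 3 each, 17.9-fold, adjusted p = 1.3e-05, higher in 3 of 3 libraries), Gzmb 40.7-fold (adjusted p = 3.85e-06), Ccl3 343-fold and Eomes 27.3-fold. Il10 rose 7.81-fold (adjusted p = 0.00166) and Mt1 13.9-fold (adjusted p = 0.000874). Without pMT-10 no-zinc CD4 replicate 2 the folds were 817 for Ccl3 and 22.7 for Mt1. Klrb1c, the gene of the NK receptor NK1.1, fell from 171 ± 11.8 to 9.44 ± 5.15 CPM (log2 -4.19, adjusted p = 4.12e-06). Klrc2 fell by 4.35, Klrk1 by 3.67 and Zbtb16, the factor of innate-like T cells, by 4.19. The ratio of mean CPM for Zbtb16 was 0.0532, and 0.0229 and 0.0797 without zinc-fed pMT-10 CD4 replicates 1 and 3. The NK list (2 rose and 5 fell of 10, adjusted p = 0.0182, and adjusted p = 0.3 with an estimated correlation) was lost without zinc-fed pMT-10 CD4 replicate 2 (0.0636) and with library size only (0.0618). The gamma-delta and innate-like list (3 of 5 fell, adjusted p = 0.0218, and adjusted p = 0.0985 with an estimated correlation) was lost with library size only (0.056). Against zinc-fed C57BL/6 neither list passed (camera adjusted p = 0.238 and 0.245). Both stood higher in pMT-10 CD4 cells without zinc than in zinc-fed C57BL/6 (camera adjusted p = 0.000346 and 0.00319), where Klrb1c averaged 39.9 CPM. The size of these falls thus depends on the control. Tbx21 stood at 62.2 ± 6.47 against 85.1 ± 11.1 CPM (log2 -0.45, adjusted p = 0.135).

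Here 2125 genes were called in CD4 cells, 1061 higher and 1064 lower, and with a 2-fold minimum 478 and 609. Interferon-gamma response genes rose (15 of 24, 0 fell, 21 over the list alone, camera adjusted p = 1.37e-11, and 0.0414 with an estimated correlation), with Serpina3g up 4.26-fold. Type I interferon-stimulated genes fell (16 of 30, 3 rose, 17 and 4 over the list alone, camera adjusted p = 0.00383, and adjusted p = 0.3 with an estimated correlation), with Slfn5 down by 2.21, Oasl1 by 2.42 and Cmpk2 by 1.2. Against zinc-fed C57BL/6 this list did not pass (camera adjusted p = 0.784), and it differed between the CD4 control groups (camera adjusted p = 2.37e-17). Naive and quiescence genes fell (15 of 18, camera adjusted p = 2.69e-11, and adjusted p = 0.176 with an estimated correlation), as Klf3 did by 1.81. The ratio of mean CPM for Klf3 was 0.286, and 0.18 without zinc-fed pMT-10 CD4 replicate 2. Effector genes (15 rose and 6 fell of 28, adjusted p = 0.000724, and adjusted p = 0.3 with an estimated correlation) included Ccl4 up 169-fold (418-fold without pMT-10 no-zinc CD4 replicate 2) and Klrd1 down by 3.39. Coinhibitory genes (9 rose and 1 fell of 15, 1.48e-05, and adjusted p = 0.158 with an estimated correlation) included Lag3 up 41-fold. Cell cycle genes (17 of 29 rose, 2.54e-10, and adjusted p = 0.0907 with an estimated correlation) included Birc5 up 6.23-fold. Glycolysis (7 of 12 rose, 2.22e-05, 0.0414 with an estimated correlation), T cell identity (7 of 12 rose, 6.21e-05, 0.0414) and IL-10 and STAT3 signalling (9 rose and 3 fell of 18, 0.00272, 0.0414) passed both ways, with Pfkp, Cd3g and Bcl3 up 2.87-fold, 2.26-fold and 3.3-fold. Regulatory T cell genes fell (6 of 13, 2 rose, 0.0168, and adjusted p = 0.176 with an estimated correlation), with Ctla4 down by 1.35.

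The activation list (8 rose and 4 fell of 21, adjusted p = 0.039, and adjusted p = 0.392 with an estimated correlation) was lost without zinc-fed pMT-10 CD4 replicate 2 (0.364). For several lists that did not pass, median, mean and camera direction parted in sign, among them zinc response (median -0.026, mean 0.452, with Mt1 the 1 gene risen of 7) and plasma cell genes (median 0.048, mean -0.718). Apoptosis (median -0.019, mean 0.04), immediate early (-0.178 and 0.083), B cell (0.132 and -0.023) and CD8 lineage genes (-0.087 and 0.294) did so too, as did platelet genes (median 2.957, camera down). Esm1 rose 97.5-fold, Nefl was at least 315-fold higher, and Chdh fell by 5.19 on the log2 scale.

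Of 106 named genes called in that CD4 contrast, 89 stayed called without any single library, and the count fell from 2125 to 1373 without zinc-fed pMT-10 CD4 replicate 1. Library size only split it into 770 higher and 1688 lower.

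In CD8 cells zinc-fed pMT-10 mice again stood above pMT-10 mice without zinc for Gzmb (141-fold, 1560 ± 571 against 11 ± 1.91 CPM, n = 3 each, adjusted p = 1.42e-06, higher in 3 of 3 libraries) and Ifng (26.8-fold, adjusted p = 1.47e-05). By pooled counts Il10 was at least 194-fold higher, Gcnt1, a glycosyltransferase gene of activated T cells, at least 304-fold and Adgrg1, an adhesion receptor gene of cytotoxic lymphocytes, at least 189-fold. The bounds were 128 for Il10 without zinc-fed pMT-10 CD8 replicate 1 and 181 for Gcnt1 without replicate 3. Prdm1 rose 65-fold (99.2-fold without pMT-10 no-zinc CD8 replicate 3), Rgs16 138-fold, Tigit 29.5-fold, Ly6a 14.4-fold and Top2a 9.98-fold. Csf1 rose 197-fold, with a fitted log2 change of 7.5, but its reads in pMT-10 no-zinc CD8 cells came from replicate 1 alone. Without that replicate the reference was at 0, so the fitted 11.68 is no bound. Cxcr4 fell by 1.35 on the log2 scale, Ccr9 by 1.65, Itgae, an epithelial residency integrin gene, by 1.14, and the lymphotoxin gene Ltb by 0.77.

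These CD8 groups gave 876 calls, 577 higher and 299 lower, and with a 2-fold minimum 410 and 83. Interferon-gamma response (17 of 24 rose, camera adjusted p = 3.14e-21, 0.00967 with an estimated correlation), coinhibitory (12 of 15 rose, 8.41e-20, 0.00967), type 1 effector (14 of 28 rose, 2.33e-12, 0.0412), cell cycle (9 of 29 rose, 2.89e-12, 0.0412) and IL-10 and STAT3 signalling genes (6 of 18 rose, 0.000222, 0.0122) passed both ways. Over all genes no member of these lists fell. Over the list alone 20, 14, 19, 20 and 8 rose in the same order, and 1 type 1 effector gene and 1 IL-10 and STAT3 gene fell. Gbp4 rose 2.99-fold and Cd274, the gene of PD-L1, 3.41-fold. Naive and quiescence genes (3 of 18 fell, 0.000371, and adjusted p = 0.443 with an estimated correlation) and activation genes (6 rose and 1 fell of 21, 0.00254, and adjusted p = 0.247 with an estimated correlation) passed by the preset test only. So did cytokine genes (5 rose and 1 fell of 17, 0.0214, and adjusted p = 0.317 with an estimated correlation), lost without pMT-10 no-zinc CD8 replicate 3 (0.0668). Glycolysis (1 of 12 rose, 0.0326, and adjusted p = 0.186 with an estimated correlation) was lost without zinc-fed pMT-10 CD8 replicate 3 (0.133) and without pMT-10 no-zinc CD8 replicate 1 (0.0894) or 3 (0.0706). Type I interferon-stimulated genes (4 rose and 2 fell of 30, adjusted p = 0.127) did not pass.

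Among markers of other cells in these CD8 libraries, the monocyte list (3 of 8 rose, adjusted p = 0.0098, 0.0412 with an estimated correlation) held Lgals3 up 29.4-fold. It was lost without zinc-fed pMT-10 CD8 replicate 2 (0.0778) or 3 (0.101) and without pMT-10 no-zinc CD8 replicate 3 (0.0668). The plasma cell list (2 of 5 rose, 0.0077, 0.0412 with an estimated correlation), again through Prdm1 and Irf4, was lost without zinc-fed pMT-10 CD8 replicate 1 (0.0569) or pMT-10 no-zinc CD8 replicate 3 (0.0784). Median and mean parted in sign for T cell identity (0.014 and -0.005), CD4 lineage (-0.069 and 0.022), CD8 lineage (0.087 and -0.035), trafficking (-0.157 and 0.108), apoptosis (0.037 and -0.021) and NK genes (-0.69 and 0.293), none of which passed.

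Of 72 named genes called in that CD8 contrast, 52 stayed called without any single library, and the count fell from 876 to 565 without pMT-10 no-zinc CD8 replicate 3.

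The control groups, pMT-10 without zinc and zinc-fed C57BL/6, were compared to show what strain, zinc and chip do without the induced transgene. Sex-linked genes led, with Xist at 926 ± 122 against 16 ± 21.1 CPM in CD4 cells and 707 ± 96.5 against 1.04 ± 1.01 CPM in CD8 cells (n = 3 each), and the Y-linked Uty, Ddx3y, Eif2s3y and Kdm5d at 0 in the pMT-10 mice. Ide, the gene of insulin-degrading enzyme, was lower in pMT-10 in both cell types (log2 -0.91, adjusted p = 0.000995 in CD4, and -1.01, 0.000253 in CD8). Adgrg5 (4.68-fold) and Plac8 (3.38-fold) were higher in pMT-10 CD4 cells. Klrb1c was higher at 171 ± 11.8 against 39.9 ± 5.08 CPM in CD4 cells (adjusted p = 0.0481). Ifng stood at 37 ± 7.26 against 49.6 ± 24.1 CPM in CD4 cells and Gzmb at 39.2 ± 9.21 against 99.3 ± 56.1 CPM, and neither was called (adjusted p = 1 and 0.794).

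Between controls 16 genes were called in CD4 cells, 9 higher and 7 lower in pMT-10, and 11 in CD8 cells, 3 higher and 8 lower. The others in CD4 cells were Setbp1, Nnt, Kdm6a, Rell1, Klrc1, Klrc2 and Cmpk2, and in CD8 cells Rell1, Slc4a8, Nnt, Neb and 5830416I19Rik. Type I interferon-stimulated genes stood higher in pMT-10 CD4 cells as a set (1 of 30 called, 10 over the list alone, camera adjusted p = 2.37e-17, and 0.0178 with an estimated correlation), and less firmly in CD8 cells (0 called, 2 over the list alone, 3.47e-07, and adjusted p = 0.224 with an estimated correlation). In CD4 cells the NK list (1 of 10 called, 0.000346, and adjusted p = 0.225 with an estimated correlation) and the gamma-delta and innate-like list (1 of 5 called, 0.00319, and 0.0356 with an estimated correlation) also stood higher. Type 1 effector genes (2 of 28 called, 0.0106, and adjusted p = 0.802 with an estimated correlation) did too, and naive (0 of 18 called, 0.0293, and adjusted p = 0.834 with an estimated correlation) and immediate early genes (0 of 16 called, 0.0244, and adjusted p = 0.448 with an estimated correlation) stood lower as sets. In CD8 cells cytokine genes stood lower as a set by the preset test only (0 of 17 called, 0.0209, and adjusted p = 0.392 with an estimated correlation).

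Of the calls between controls, 7 of 16 in CD4 cells and 7 of 11 in CD8 cells stayed called without any single library. In CD4 cells the adjusted p reached 0.29 for Klrb1c, 0.255 for Klrc1 and 0.265 for Klrc2 without zinc-fed C57BL/6 replicate 1, and 0.141 for Xist and 0.121 for Nnt without replicate 2. Without pMT-10 no-zinc CD4 replicate 1 it reached 0.416 for Cmpk2, 0.143 for Kdm6a and 0.1 for Setbp1, and without replicate 2 0.259 for Rell1. In CD8 cells it reached 0.0911 for Nnt and 0.126 for Neb without pMT-10 no-zinc replicate 1, and 0.0572 for Slc4a8 and 0.179 for 5830416I19Rik without replicate 3. The CD4 count was 10, 9 and 9 without zinc-fed C57BL/6 replicates 1, 2 and 3, and 7 without pMT-10 no-zinc replicate 1 or 2.

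Genes that differed from both controls in the same direction were counted to set aside strain, sex, zinc and chip, no single one of which separates zinc-fed pMT-10 mice from both control groups. In CD4 cells there were 1608, of which 815 rose and 793 fell, where independent calls would give 98.5 and 100, and 1 gene was called in opposite directions. In CD8 cells there were 594, of which 416 rose and 178 fell against 32.8 and 9.35, with 1 opposite. Both contrasts share the zinc-fed pMT-10 libraries. In simulated unchanged groups with that sharing, 0 genes overlapped. Groups without changed genes give almost no calls, so this 0 does not show how much sharing adds to the overlap. Noise was drawn gene by gene, so a shift common to the zinc-fed pMT-10 libraries could not arise. Simulated fold changes correlated at 0.5 in CD4 and 0.51 in CD8 cells against 0.83 and 0.71 observed, and their covariance was 0.14 and 0.16 against 1.18 and 1.04. Part of the excess may come from the shared libraries, and 3 libraries cannot be halved. Common to both cell types and both controls were 258 genes that rose, Ifng, Gzmb, Lag3, Irf1 and Bcl3 among them, and 93 that fell. The CD4 count was 1048 without zinc-fed pMT-10 CD4 replicate 1.

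**Figure D3:**
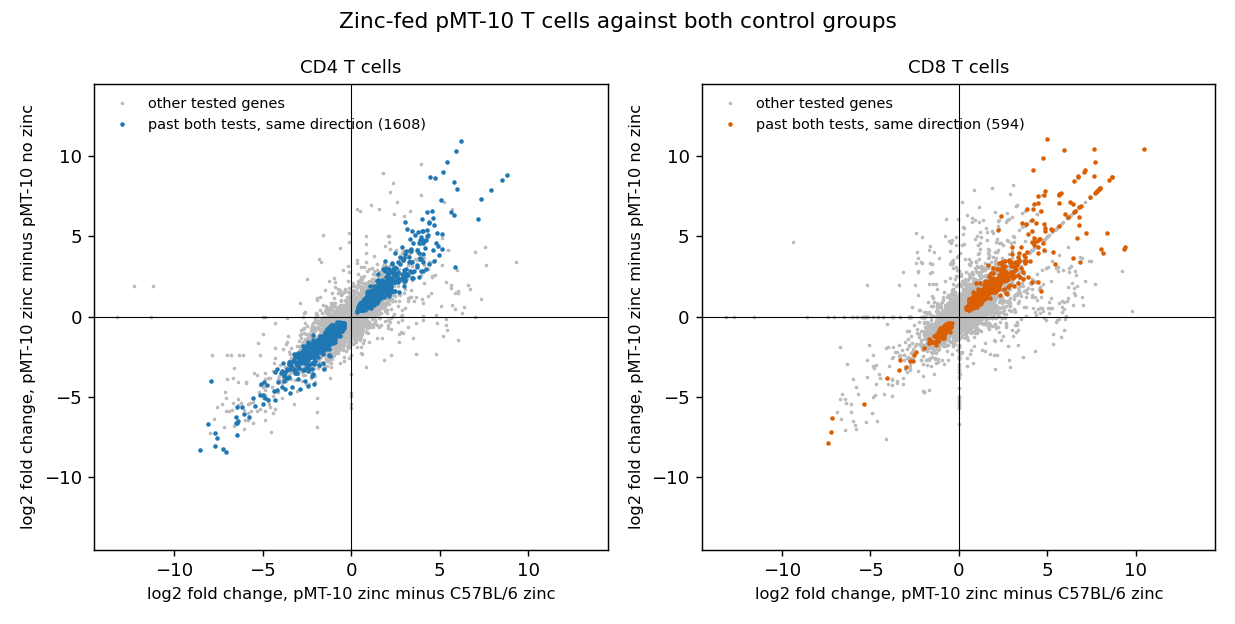
Log2 fold change of each tested gene in zinc-fed pMT-10 against zinc-fed C57BL/6 mice (horizontal axis) and against pMT-10 mice without zinc (vertical axis), for CD4 and CD8 cells. The fold changes correlated across genes at 0.83 in CD4 cells and 0.71 in CD8 cells.

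Whether the difference between zinc-fed pMT-10 and zinc-fed C57BL/6 mice was the same in CD4 and CD8 cells was tested directly. Eomes and Crtam rose in CD4 cells and were not called in CD8 cells. Eomes had a log2 change of 4.05 (SE 0.29) in CD4 and 0.66 (SE 0.26) in CD8 cells, a difference of -3.39 (adjusted p = 5.36e-05), and the T cell surface gene Crtam changed by 2.15 and -0.23, a difference of -2.38 (adjusted p = 5.36e-05). Ctla4 went opposite ways, at -1.25 in CD4 and 2.35 in CD8 cells, a difference of 3.6 (adjusted p = 0.000107). Slamf1 stood at -0.18 and 1.74, a difference of 1.92. Ifng did not differ detectably, with changes of 3.74 and 4.42 (difference 0.68, SE 0.6, adjusted p = 0.558).

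The interaction called 621 genes, 386 with the higher change in CD8 cells and 235 with the higher change in CD4 cells. Of them 388 had opposite fitted signs, 19 were called in opposite directions, 380 were called in CD4 cells alone, 128 in CD8 cells alone and 51 in both with the same sign. Naive and quiescence genes differed (8 of 18 called, all with the higher change in CD8 cells, camera adjusted p = 1.38e-07, and adjusted p = 0.467 with an estimated correlation), as did coinhibitory genes (7 of 15, likewise, 0.00143, and adjusted p = 0.467 with an estimated correlation). Regulatory T cell genes (6 higher and 1 lower of 13, 0.00102), T cell identity (5 of 12 lower, 0.00036), glycolysis (3 of 12 lower, 0.00141) and plasma cell genes (2 of 5 higher, 0.0138) each had an adjusted p = 0.0819 with an estimated correlation. Type I interferon-stimulated genes (2 of 30 higher, 0.00271, and adjusted p = 0.508 with an estimated correlation) passed by the preset test, and interferon-gamma response genes (5 higher and 1 lower of 24, 0.185) did not. Against zinc-fed C57BL/6, 496 genes were called in the same direction in both cell types, 336 up and 160 down, where independent calls would give 59.7 and 33.3. Fold changes in the cell types correlated across genes at 0.37. Type 1 effector genes (6 higher and 4 lower of 28, adjusted p = 0.992) had a median of 0.046 and a mean of 0.332 with camera down, and cytokine genes (0.982) a median of -0.004 and a mean of 0.639.

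The interaction count was 255, 837 and 386 without zinc-fed pMT-10 CD4 replicates 1, 2 and 3, 405 without zinc-fed pMT-10 CD8 replicate 2, 328 and 373 without zinc-fed C57BL/6 CD4 replicates 1 and 2, and 350 without zinc-fed C57BL/6 CD8 replicate 3. Library size only gave 648 higher and 120 lower.

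CD8 and CD4 cells were compared within each kind of mouse as a check of the sort and a background for the interaction. Cd8b1 was 88.8-fold higher in CD8 cells of zinc-fed C57BL/6 mice (n = 3 each, adjusted p = 1.79e-15), 83.6-fold in zinc-fed pMT-10 and 106-fold in pMT-10 without zinc. Map6 had 0 counts in CD8 cells of both controls and was higher in CD4 cells by at least 582-fold and 706-fold, as were the interleukin-9 receptor gene Il9r in zinc-fed C57BL/6 (at least 330-fold) and Ccr6 in pMT-10 without zinc (at least 1750-fold). Slc6a19, an amino acid transporter gene, was 77-fold and 795-fold higher in CD8 cells of the control groups. In zinc-fed pMT-10 mice the NK receptor gene Klra7 stood at 40.2 ± 21.1 CPM in CD8 and 0.0513 ± 0.0459 CPM in CD4 cells (adjusted p = 1.31e-06), and Areg, a repair growth factor gene, was at least 136-fold higher in CD4 cells.

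Calls between cell types numbered 2511 in zinc-fed C57BL/6 (1050 higher and 1461 lower in CD8), 3178 in zinc-fed pMT-10 (1512 and 1666) and 2458 in pMT-10 without zinc (1012 and 1446). Regulatory T cell genes were lower in CD8 cells, 12 of 13 in each kind of mouse, with camera adjusted p of 7.2e-15, 1.86e-11 and 2.08e-14 (0.00111, 0.00414 and 0.00129 with an estimated correlation). Naive and quiescence genes were higher in CD8 cells, 8, 17 and 14 of 18, with adjusted p of 3.78e-05, 1.41e-13 and 1.67e-07, and adjusted p = 0.422, 0.12 and 0.268 with an estimated correlation. With library size only, the splits were 1845 and 1354 in zinc-fed pMT-10 and 750 and 1673 in pMT-10 without zinc.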

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

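The tests of cell contamination, of shared libraries and of a mixed library below were chosen after the results were seen, as were those that set both controls side by side; the counts of other splits were planned before the data were examined. A first run counted a split and its mirror as separate splits. Counting each once replaced that after its result was seen, and it turned the outcome for the interaction from excluding chance to not excluding it.

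The change between zinc-fed pMT-10 and zinc-fed C57BL/6 mice differed between CD8 and CD4 cells for 621 genes by the interaction test. Of the 14 called genes named here, 8 were taken because their p in this same test was the smallest, so their calls follow from the choice. Dntt, Gpr15, 2900026A02Rik and Tox2 were taken for large changes in a contrast that enters this test, so their calls are not free of the choice either. Il10 and Gzmb were fixed before the data were examined. Genes with a more positive change in CD4 cells were Crtam (difference of log2 changes -2.38), Cst7 (-1.81), a regulator of granule proteases, Eomes (-3.39) and Sytl3 (-2.53). Genes with a more positive change in CD8 cells were Gm14085 (3.11), Ctla4 (3.6), Slamf1 (1.92), Gzmb (2.29), Dntt (3.21), Gpr15 (2.79), 2900026A02Rik (5.26) and Tox2 (4.82), a factor that exhausted T cells express. Map6 (8.47) and Il10 (8.68) also did, but both have a group at 0, so their fitted values are no bounds. The difference for Gzmb (adjusted p = 0.0443) lost its call without any 1 of 9 libraries and reached 0.0947 without zinc-fed C57BL/6 CD8 replicate 2. That for Tox2 was 9.41 at its highest when 1 library was left out. Tox2 reads in zinc-fed C57BL/6 CD8 cells came from replicate 3 alone, so a fitted value without that library is no bound. Over the 100 pairs of a CD4 and a CD8 split, 6 gave as many genes as the real 621, with 1057 the highest other among them. Swapping the CD8 group names with CD4 kept, which these pairs leave out, gave 2326, so chance is not excluded by this count. The splits with more genes kept the real groups in 1 cell type and mixed them in the other, and the highest with both mixed was 1, which points to the strong group structure within each cell type.

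Genes that rose in CD8 cells of zinc-fed pMT-10 mice were often ones that CD4 cells hold more of in mice without zinc. Of the 643, 318 (49.5%) were lower in CD8 than CD4 cells without zinc, against 12.8% of all genes and 12.1% of the genes that fell. CD4 cells in the CD8 sort are argued against, since Cd4 in these CD8 libraries stood at 0.0213% of its CD4 level where the median gene would need 34%. Regression to the mean through shared libraries is argued against as the whole cause, since the groups without zinc share no library with the contrast. In them the genes that rose had a median CD8 minus CD4 difference, less that of all genes, of -0.78 (SE 0.07 from resampling genes, not mice). The shares of all genes and of genes that fell were not matched to the 643 on level in CD8 cells. Genes near 0 there can rise but not fall, so part of the excess may come from level. A real shift of CD8 cells towards a programme that CD4 cells carry, or a change in which CD8 cells are present, stays open as a hypothesis.

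Many genes changed against both controls, which may follow from IL-10 but was weighed against the other differences between the groups. Sex or strain alone is argued against, since 76% of the CD4 and 59.6% of the CD8 calls against C57BL/6 were also called within pMT-10. The chip or zinc alone is argued against, since 75.7% of the CD4 and 67.8% of the CD8 calls within pMT-10 were also called within 1 chip. A property of the 3 zinc-fed pMT-10 mice themselves, such as cage or litter, and an effect of zinc peculiar to this strain stay open and untested.

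Zinc-fed C57BL/6 CD4 replicate 3 held more Xist (40.1 CPM) than replicates 1 and 2 (0.456 and 7.49 CPM), with Ddx3y at 177 CPM, and more Gzmb (159 against 48.3 and 90.2 CPM) and Ccl3 (20.7 against 2.2 and 6.95 CPM). A candidate explanation is RNA or reads of zinc-fed pMT-10 CD4 cells. Over 26 induced genes the median share needed was 7.46% (quartiles 5.16 and 9.82), near the 6.15% that Xist gives. CD8 cells are argued against, since Cd8a was -3.49 CPM off the other replicates where 146 CPM would be needed, and pMT-10 CD4 cells without zinc are argued against by the lower quartile of 5.16%. An activated state of that mouse together with a separate source of Xist stays open, and such a mixture would shrink the CD4 contrast with zinc-fed C57BL/6.

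For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In each, only the real split of the 10 gave as many genes. The real and highest other counts were 2115 and 0 (CD4) and 997 and 2 (CD8) against zinc-fed C57BL/6, and 2125 and 0 (CD4) and 876 and 2 (CD8) against pMT-10 without zinc. Between controls they were 16 and 0 (CD4) and 11 and 2 (CD8), and between cell types 2511, 3178 and 2458, each with 0. For genes shared by CD4 and CD8 cells, 1 of 100 pairs of splits gave as many as 496, with 1 the highest other. Cells of both types came from the same mice, so the CD4 and CD8 splits are not independent. With mice as the unit the splits are again too few, so chance is not excluded. For genes changed against both controls, 2 of 100 regroupings gave as many in CD4 (1608, highest other 1608) and 2 in CD8 cells (594, highest other 602), which excludes chance there. The other regrouping as large in each cell type kept the zinc-fed pMT-10 libraries together and mixed the controls.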

How the results depend on the processing

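Leaving out genes on X and Y and leaving out zinc-fed C57BL/6 CD4 replicates 2 and 3 together were tests chosen after the data were seen; the other alternatives were planned. No called result reversed under any alternative run. Of the results for named genes, 9394 kept their side of the threshold, 425 lost it and 175 gained it, and of those for lists 1761, 66 and 32. Under other size factors, a stricter filter or robust fitting off, every count of called genes stayed within 1.5 times its value. Library size only kept them so too, but shifted the median log2 change of all genes to -0.155 (CD4 against zinc-fed C57BL/6), -0.196 (CD4 against pMT-10 without zinc) and 0.206 (the difference between cell types).

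With a 2-fold minimum, which by construction calls fewer genes, the counts were 1051 (CD4) and 503 (CD8) against zinc-fed C57BL/6, 1087 and 493 against pMT-10 without zinc, and 1407, 1595 and 1371 between cell types in zinc-fed C57BL/6, zinc-fed pMT-10 and pMT-10 without zinc. Genes changed against both controls were 822 and 329, and those shared by the cell types 246. At an adjusted p of 0.01, stricter by construction, the counts in the same order were 1223, 464, 1244, 447, 1498, 1957, 1469, 942, 311 and 255, with 8 between controls in CD4 cells and 171 for the difference between cell types.

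limma-voom with quality weights gave 3309 and 3915 in CD4 cells against the 2 controls, 25 between controls in CD4 cells, 960 for the difference between cell types and 2697 against both controls in CD4 cells. DESeq2 gave 33 (CD4) and 42 (CD8) between controls and 1030 for the difference, and no filter 83, 107 and 1055. The cause was not tested for any of these. With libraries of the same cell type only, CD8 counts were 613, 559 and 394 (against zinc-fed C57BL/6, against pMT-10 without zinc and against both), and with the groups compared only 588 in CD8 cells and 410 for the difference. The CD4 counts against the 2 controls went the other way, to 2738 and 2745 with the cell type only and 2253 and 3042 with the groups compared only, and the cause was not tested. Without X and Y genes, 8 (CD4) and 6 (CD8) were called between controls. The sex-linked genes were removed, and in CD4 cells Cmpk2 (adjusted p = 0.0749) and Klrb1c (0.0782) lost their calls too. Without zinc-fed C57BL/6 CD4 replicates 2 and 3, which leaves 1 library assumed to vary like the other groups, the counts were 1223 in CD4 cells, 1396 between cell types, 997 against both controls and 318 shared. In that fit Il10 (adjusted p = 0.253), Mki67 (0.0801) and the regulatory T cell list (0.0974) lost their calls in CD4 cells, while the log2 changes of Il10 (1.57 against 1.79) and Mki67 (1.76 against 1.72) stayed about as large.

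Leaving out 1 library at a time, counts against zinc-fed C57BL/6 ran from 1377 (without zinc-fed pMT-10 CD4 replicate 1) to 2160 in CD4 cells and from 587 (without zinc-fed C57BL/6 CD8 replicate 3) to 920 in CD8 cells. Against pMT-10 without zinc they ran from 1373 (without zinc-fed pMT-10 CD4 replicate 1) to 2103 and from 565 (without pMT-10 no-zinc CD8 replicate 3) to 755. Between controls in CD4 cells they ran from 7 (without pMT-10 no-zinc replicate 1 or 2) to 12, with 10, 9 and 9 without zinc-fed C57BL/6 replicates 1, 2 and 3, and in CD8 cells from 8 to 13. The difference between cell types ran from 255 (without zinc-fed pMT-10 CD4 replicate 1) to 837, with 386 without replicate 3, 405 without zinc-fed pMT-10 CD8 replicate 2, 328 and 373 without zinc-fed C57BL/6 CD4 replicates 1 and 2 and 350 without zinc-fed C57BL/6 CD8 replicate 3. Genes changed against both controls ran from 1048 (without zinc-fed pMT-10 CD4 replicate 1) to 1678 in CD4 and from 430 to 524 in CD8 cells. Those shared ran from 345 to 483. These fits have fewer samples. Of levels, 34 stayed within 1 SD and 2 moved when CPM used total counts, Cd4 in CD4 cells to 3090 CPM in zinc-fed pMT-10 and 1800 CPM in pMT-10 without zinc. No paired analysis was possible because the labels do not say which CD4 and CD8 libraries came from the same mouse. In simulated data of this depth and size, 50.8% of 2-fold and 7.46% of 1.5-fold changes were called, so small changes can be missed. Few genes were changed in that simulation, so these shares need not hold for contrasts with many changed genes.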

Other observations

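All tests in this part were chosen after the results were seen. Genes that rose in CD4 cells of zinc-fed pMT-10 mice showed little of the converse of the CD8 pattern: 119 of 1051 (11.3%) were higher in CD8 than CD4 cells without zinc, against 8.94% of all genes.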
